A study of Mus musculus with 2 samples.

How the data were processed

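Gene expression was measured in primary mouse myoblasts with 2 arrays, 1 from cells kept in medium alone and 1 from cells given Wnt3a. Per the labels' protocols, biotin-labelled cRNA was made from Trizol-extracted total RNA with an Affymetrix 3′ expression kit, which labels RNA from its 3′ end. The deposited table gives 1 intensity per probe set and array. Per the submitters' processing notes, the tools were RMA, affy and limma, with no versions, order or settings named. RMA in general corrects background, quantile normalizes probes and summarises the probes of a set. The deposited intensities ran from 7.09 to 37075 in the control array and from 7.07 to 36604 in the Wnt3a array, so they were on a linear scale and not the log2 scale that RMA usually gives. How they were brought to a linear scale is not given in the sources used here. The median intensity was 57.9 in the control array and 58.7 in the Wnt3a array. Identical values on both arrays were found for 1689 of 45101 probe sets (3.74%). No detection call was used here, and the genome build is not given in the sources used here.

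The design had been written for log2 values, with log2(intensity + 1) if the values proved linear, and this second form was used. A pseudocount of 1 slightly shrinks differences of dim probe sets. The 64 control probe sets were left out of the gene comparison. Of the other 45037 probe sets, 34945 were assigned to 1 gene by GEO's platform annotation, 932 to several and 9160 were unnamed here. For 34741 of the 34945 the Entrez identifier was found in the RefSeq gene table of GRCm38.p6, which changed no symbol. No coordinates were taken from that table. Each of the 18193 genes was represented by its probe set with the highest mean over both arrays. A gene counted as measured where that probe set reached a floor of 6 on the log2 scale (an intensity of 63) in at least 1 array, which held for 11397 genes. The floor is a fixed brightness and not a detection limit.

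With 1 array per group there is no replicate, no p-value and no test of any gene. Differences are Wnt3a minus control on the log2 scale. Genes with a difference of at least 1 in size (2-fold) were counted. These counts use the measured values. Where the dimmer array lay below the floor, the fold in the text is given as "at least", against the floor, and can be under 2. The only repeat measurement is between probe sets of the same gene, which shows noise between probes only. Noise between hybridisations, labellings or cultures has no repeat here. For 31 gene lists written before the data were examined, the median difference of the measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile under 2.5 or over 97.5 was taken as standing apart. This describes these 2 arrays and is no test of the treatment. Lists with under 5 measured genes got no percentile.

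The text names the 15 genes highest with Wnt3a over control and the 15 lowest, by log2 difference, among measured genes whose probe sets at the floor had 1 sign, up to 12 members with the largest differences of 3 main lists (both Wnt target lists and the myogenic regulators), up to 4 members of each other list, and Axin2, Lef1, Myod1, Myf5, Pax7 and Myog always. Alternatives planned before the data were examined were no floor, a floor of 8, a floor on the mean, the mean of all probe sets, leaving out probe sets that can match several transcripts, removal of a loess trend (span 0.3), a median difference of 0, quantile normalization, thresholds of 1.5-fold and 3-fold, random lists without matching and list means. Logarithms without a pseudocount, values raised to the floor and scaling on the spike-in controls were added after seeing the data.

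The procedure was tested on simulated data for the comparison of Wnt3a against control, with 11369 measured genes. Of 50 genes simulated at each fold, 0 at 1.5-fold, 27 at 2-fold, 50 at 3-fold and 50 at 4-fold were counted as 2-fold changed, and 0 of 11169 unchanged genes were. Of 100 unchanged lists of 20 genes 3 stood apart, and of 100 lists shifted up by 0.1 on the log2 scale 77 did. The simulated noise was normal, independent between probe sets and equal at every brightness, with an SD from the central spread of observed differences. It held no wider tails, no extra noise of dim probe sets and no differences between cultures. These counts are therefore no false-positive rate for the real arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.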

Results

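Primary myoblasts, the muscle precursor cells that proliferate and fuse into muscle fibres, had been isolated from newborn Sv129 mice and cultured on laminin and collagen. They were then kept for 4 hours in DMEM with 2% horse serum, a low-serum medium, either alone (control) or with 100 ng/ml of Wnt3a, a secreted ligand that stabilises β-catenin. The comparison asks which transcripts differ after this exposure. There was 1 array per condition, so every value below is a single measurement and no difference has a replicate check. The number of arrays limits the precision. Probe sets at or above the floor made up 48.2% of those on the control array and 48.5% of those on the Wnt3a array.

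Few genes differed strongly between the arrays, and most of those that did were higher with Wnt3a. Of 11397 measured genes, 29 were at least 2-fold higher and 7 at least 2-fold lower, together 0.316% of the measured genes. With values below the floor raised to it, an alternative chosen after seeing the data, the counts were 26 and 6. Among the genes with large differences were higher Calcb, Axin2, Bhlhe40, Car2, Fst, Pfn2 and Ppargc1a and lower Scgb1a1, Id4, Epha4 and Myc. Of these, Calcb and Ppargc1a were below the floor in the control and Scgb1a1 with Wnt3a. The central 95% of measured genes lay between -0.33 and 0.33 on the log2 scale, and the pooled SD between probe sets of the same gene was 0.12 (5084 genes with 2 or more probe sets at the floor). Of the 36 changed genes, 16 had at least 2 such probe sets, and in all 16 the probe sets had 1 sign, against 54.7% of all genes with 2 or more. The other 20 rested on 1 probe set. Agreement in sign was likely beforehand for genes picked by a difference of at least 1, against an SD of 0.12. That SD is pooled over all 5084 genes and is no error of a single fold. Among the changed genes it was, for example, 0.017 for Syt13 and 1.34 for Axin2. The values across measured genes had a Pearson correlation of 0.995 between the arrays, which is across genes and not across replicates.

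**Figure D1:**
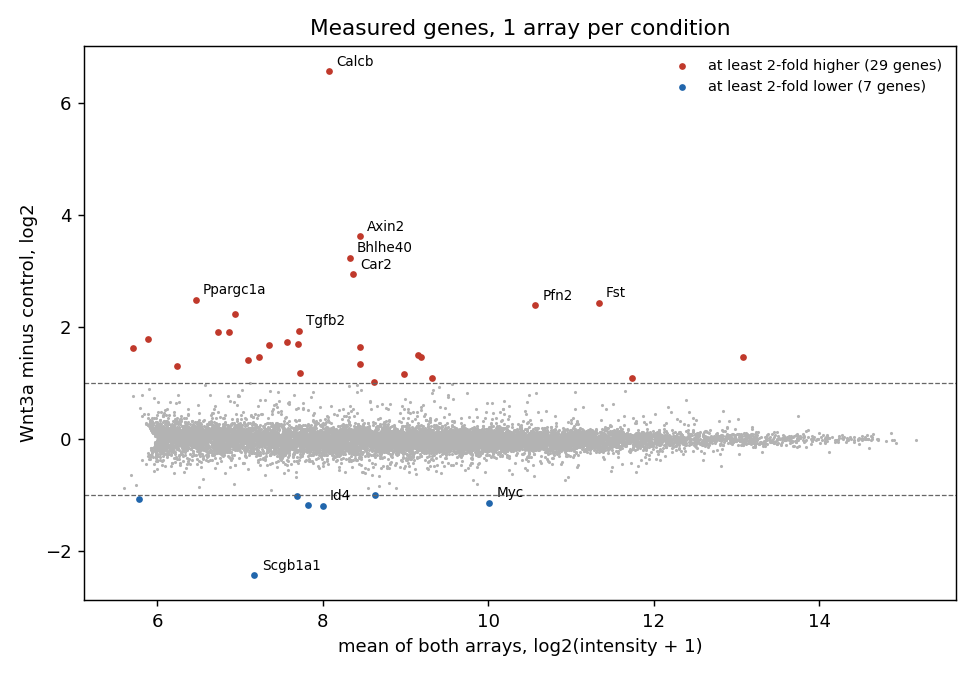
Difference between the arrays (Wnt3a minus control, log2) against the mean of both arrays, log2(intensity + 1), with 1 point per measured gene and dashed lines at a 2-fold difference. The 29 red genes lie at or above the upper line and the 7 blue genes at or below the lower line, with Calcb highest at 6.56 and Scgb1a1 lowest at -2.43.

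These directions are relative to the bulk of the genes, since the median difference over all probe sets was 0 in the deposited values. The spike-in controls were lower on the Wnt3a array. The 18 probe sets of the hybridisation spike-ins had a median difference of -0.17 and the 24 of the poly-A spike-ins one of -0.21, and all 42 were negative. Scaling on these controls, an alternative chosen after seeing the data, would add 0.19 to every difference, so that negative differences smaller than this in size would change sign, also those of single genes below. It gave 48 genes at least 2-fold higher and 1 lower, a share of higher genes of 98.0% in place of 80.6%.

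Axin2 and a few other genes of the Wnt feedback and consensus target list were higher with Wnt3a, while the other measured members differed by less than 1.5-fold, in both directions. Axin2, a scaffold of the β-catenin destruction complex and a textbook Wnt target, went from 6.64 to 10.25, a 12.2-fold difference (log2 difference 3.61, while its other probe set was below the floor in the control and reached 6.03 with Wnt3a). Lgr5, an R-spondin receptor, was at least 1.85-fold higher (5.58 to 6.89), with 0.30 on a probe set below the floor on both arrays. Bambi, a decoy receptor for BMP and TGF-β, was 1.58-fold higher and Zfp703, a transcriptional repressor, 1.52-fold higher, the latter with 0.11 on another probe set and -0.19 on one below the floor. Among the 16 measured of the 28 feedback and consensus targets, 11 were higher, 4 of them by at least 1.5-fold, and 5 were lower, none by that much. The list's median difference of 0.16 lay above all 10000 matched random lists (percentile 100), and its percentile stayed at 99.87 or more in all 13 alternative settings. Fzd7 (0.37, and 0.24 as a mean over its probe sets), Sfrp2 (0.35), Znrf3 (0.19), Lgr6 (0.18, and 0.02 on its other probe set) and Kremen1 (0.13) were higher by less, and Nkd2 (-0.21), Nkd1 (at least 1.13-fold) and Ccdc88c (-0.15) were lower. The inhibitor genes Notum, Rnf43, Dkk1 and Wif1 were below the floor on both arrays. Lef1, a β-catenin partner and often a target itself, differed by -0.13, with 0.12 on a second probe set that lay below the floor.

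Genes reported elsewhere as Wnt targets in some cell types did not share a direction. Fst, which encodes the activin and myostatin antagonist follistatin, was 5.39-fold higher (10.12 to 12.55, with 2.43 and 2.68 on its 2 probe sets), and Nrcam, a neuronal cell adhesion gene, was 3.22-fold higher, a difference that became 0.84 as a mean over all its probe sets. Myc, the growth-promoting transcription factor, was 2.19-fold lower (10.58 to 9.44, 1 probe set). Snai1 was higher (0.66) while its relative Snai2 was lower (-0.73), and both encode repressors of epithelial genes. Enc1 (0.49) and Edn1 (at least 1.30-fold) were higher, and Sox9 (-0.64, and -0.38 as a mean over its probe sets), Sox4 (-0.49, from -0.75 to -0.05 on 6 probe sets), Id2 (-0.43), Ccn4 (-0.33, and -0.15 on its other probe set) and Jun (-0.32) were lower. Of the 36 measured genes, 10 of which also stand in other lists, 16 were higher and 19 lower. The median of -0.054 lay at percentile 1.41 but the mean was 0.049, and under spike-in scaling the median was 0.14 at percentile 1.37. The list did not stand apart in 7 of 13 settings.

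The pathway's own components were slightly higher as a group. Fzd1, a Wnt receptor, was 1.98-fold higher, with 0.20 on its other probe set, and the Groucho-type corepressors Tle1 and Tle4 were 1.83-fold and 1.46-fold higher, while Fzd5 was at least 1.22-fold lower. Of 30 measured receptors and core components 19 were higher and 11 lower, with a median of 0.048 at percentile 98.25, which ended within the random range in 3 of 13 settings. Wnt5a, a ligand best known for signalling without β-catenin, was at least 1.72-fold higher, reaching 6.78. Its dimmer probe sets, below the floor on both arrays, gave 0.78, 0.40 and 0.32. Wnt6 (0.41), Sfrp1 (0.35) and Wls (0.29), the last a carrier for Wnt secretion, were higher too, with 0.14 and 0.15 on other probe sets of the latter pair. Of the 12 measured ligands and secreted inhibitors 10 were higher, with a median of 0.21 at percentile 99.98, and the list left the upper range in 2 of 12 settings.

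The largest difference was that of Calcb, which encodes the β form of calcitonin gene-related peptide. It was at least 40.9-fold higher with Wnt3a, at 11.35 against 4.79 in the control, on 1 probe set. Bhlhe40, a circadian and hypoxia-related repressor, was 9.40-fold higher, and Car2, a carbonic anhydrase, 7.66-fold, both on 1 probe set. Ppargc1a, the coactivator PGC-1α that drives mitochondrial biogenesis, was at least 3.27-fold higher, and all of its 5 probe sets that reached the floor with Wnt3a were below it in the control. Pfn2, an actin-binding profilin, was 5.21-fold higher (2.32 to 2.39 on 3 probe sets). Syt13, a synaptotagmin, was at least 4.15-fold higher and Tgfb2, a TGF-β ligand, 3.82-fold higher (3 probe sets of 1 sign). The transcription factor Osr2 was at least 3.21-fold and Lifr, the receptor for leukaemia inhibitory factor, at least 3.53-fold higher on their brightest probe sets. Dimmer probe sets, below the floor, gave 0.02 for Osr2 and 0.37 and 0.73 for Lifr. Rasl11b, a small GTPase, was 3.19-fold higher. A probe set annotated to Mir133b, which detects a longer transcript and not the mature microRNA, was 3.31-fold higher.

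**Figure D2:**
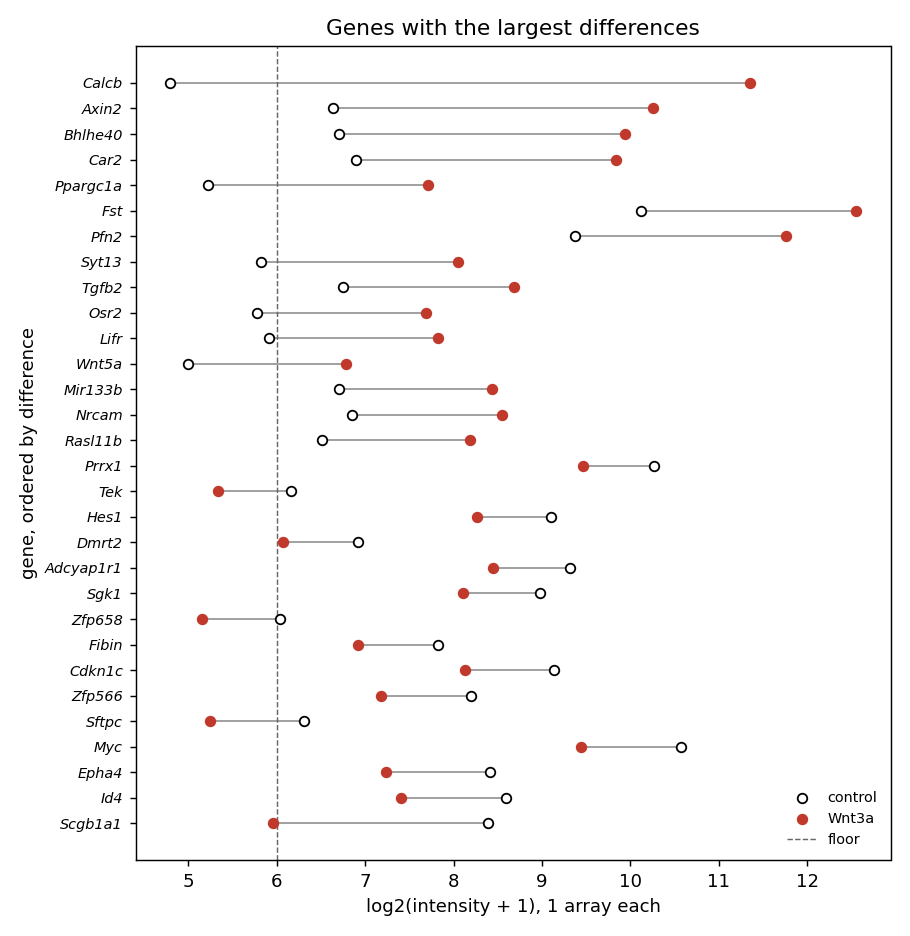
Levels in the control (open circles) and Wnt3a (red circles) arrays, as log2(intensity + 1), of the 15 genes with the largest positive and the 15 with the largest negative difference, with the floor of 6 as a dashed line. Calcb goes from 4.79 to 11.35 and Fst from 10.12 to 12.55, and Scgb1a1 from 8.39 to 5.96.

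Lower transcripts with Wnt3a showed smaller differences. Scgb1a1, a secretory protein of airway epithelium, was at least 5.23-fold lower, at 8.39 in the control and 5.96 with Wnt3a. Sftpc, a lung surfactant gene, was at least 1.24-fold lower (6.31 to 5.24), with 0.04 on a probe set below the floor on both arrays. Id4, an inhibitor of basic helix-loop-helix factors, was 2.28-fold lower (-0.31 to -1.19 on 3 probe sets), and Epha4, an ephrin receptor, 2.26-fold lower (3 probe sets of 1 sign). As means over all probe sets these became -0.87 and -0.68. Cdkn1c, the cell cycle inhibitor p57, was 2.00-fold lower and Zfp566, a zinc finger gene, 2.02-fold. Hes1, a Notch target, was 1.79-fold lower, the kinase gene Sgk1 1.83-fold, the neuropeptide receptor gene Adcyap1r1 1.83-fold (-0.25 to -0.87 on 3 probe sets), and the mesenchymal homeobox gene Prrx1 1.75-fold (-0.50 to -1.18 on 5 probe sets). Dmrt2, a transcription factor gene of somite development, was 1.80-fold and Fibin 1.87-fold lower. Tek and Zfp658 crossed the floor and were lower by at least 1.12-fold and 1.02-fold.

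Of the genes that define myoblasts, Myod1 and Pax7 differed little between the arrays, while other muscle transcription factors differed in both directions. Myod1, the myogenic determination factor, was at 13.41 and 13.28, and Pax7, the satellite cell factor, at 11.20 and 11.08, with 0.12 in the other direction on its second probe set. Myf6 (1.69-fold), Mef2a (1.49-fold, 0.47 to 0.65 on 6 probe sets) and Myf5 (1.40-fold), all muscle transcription factors, were higher. Myog, which marks entry into differentiation, was 1.41-fold lower, as were the surface genes Vcam1 (1.55-fold), Sdc4 (1.51-fold, but -0.20 as a mean over its probe sets), Met (1.37-fold) and Itga7 (1.20-fold), and the homeobox gene Six4 (-0.24). Eya1 (0.30), Meox1 (at least 1.05-fold) and Cxcr4 (0.27) were higher. Of the 21 measured myogenic regulators 13 were higher and 8 lower, with a median of 0.062 at percentile 99.24, and the list ended within the random range in 3 of 13 settings. Genes of muscle differentiation and contraction were slightly higher as a group, with 27 of 43 higher and a median of 0.056 (percentile 99.86), and ended within the random range in 2 of 13 settings. The largest among these were Myh1 (0.35), Cav3 (0.32) and Des (0.32, and 0.11 as a mean over its probe sets), and the only member changed by at least 1.5-fold was Cdkn1c, on the low side.

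Genes of ribosome production were lower as a group relative to other genes of like brightness. Of the 22 measured genes of ribosome biogenesis and the nucleolus 21 were lower, none by 1.5-fold, among them Rrs1 (-0.36), Srm (-0.25), Gnl3 (-0.25) and Nop2 (-0.20). The median of -0.11 lay below all 10000 matched lists (percentile 0), and under spike-in scaling the median turned positive (0.079) with the percentile still at 0. Genes of G1/S and DNA replication were lower in 22 of 28 cases, with a median of -0.079 at percentile 0.17, which became 0.11 at percentile 0.30 under spike-in scaling. This call ended when probe sets that can match several transcripts were left out. Orc1 (-0.44, but 0.05 on its other probe set), Cdc6 (-0.35), Ccne2 (-0.29) and Cdt1 (-0.25), which license or start replication, differed most. The G2/M genes did not stand apart (17 of 25 lower, median -0.041, percentile 12.7), with Kif20a (-0.16), Nusap1 (-0.16) and Ttk (-0.15) lower and Cenpf higher on its brightest probe set (0.23) but lower on another (-0.28). With the mean of all probe sets, the list did stand apart on the low side (percentile 0.23). The cytosolic ribosomal proteins did not stand apart either (median -0.0049, mean 0.0027, percentile 52.8), with Rpl27a at -0.24, Rps9 at 0.16 (-0.07 on another probe set), Rpl11 at 0.14 and Rps6 at -0.07.

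**Figure D3:**
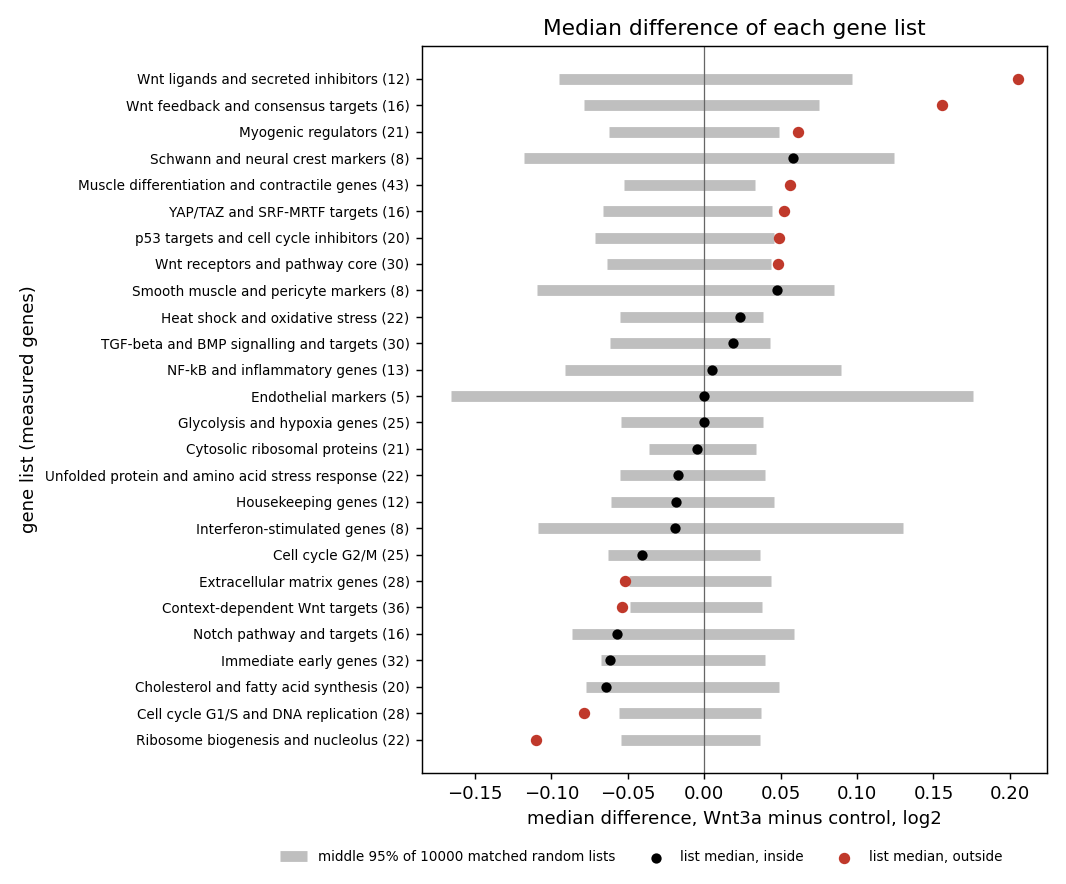
Median difference (Wnt3a minus control, log2) of the 26 gene lists with at least 5 measured genes (number in parentheses), with the middle 95% of 10000 random lists matched on mean expression as grey bars. The Wnt feedback list (0.16) and the ligand list (0.21) lie to the right of their bars, and the ribosome biogenesis list (-0.11) to the left, where spike-in scaling would give it 0.079.

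Of the 26 lists with a percentile, 11 stood apart, 7 on the high and 4 on the low side. Lists of independently drawn genes would give 1.3. Genes of a list can vary together between any 2 cultures, and some lists share members, so the count does not exclude chance. The other 3 of the 11 had median shifts of about 0.05. Targets of YAP/TAZ and SRF, led by Ccn1 (0.56, from 0.01 to 0.59 over its probe sets), Acta2 (0.33) and Vcl (0.27), with Fhl2 at -0.25, had a median of 0.052 (percentile 98.79, within the range in 3 of 13 settings). The p53 targets and cell cycle inhibitors, led by Pmaip1 (0.57), Btg1 (0.35) and Cdkn1b (0.35, and 0.16 as a mean over its probe sets), with Gadd45b at -0.34, had a median of 0.049 (percentile 98.06), which fell within the range in 5 of 13 settings. Extracellular matrix genes had a median of -0.051 (percentile 2.12), which ended within the range in 5 of 13 settings and became 0.14 under spike-in scaling. Their largest differences were Timp1 (0.49), Loxl1 (-0.32, and -0.07 as a mean over its probe sets), Col4a1 (-0.26, and -0.07 on its other probe set) and Adamts1 (-0.25).

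The medians of the remaining signalling and metabolic lists lay within the random range. The 30 measured genes of TGF-β and BMP signalling, with Fst, Tgfb2, Id4 and Bambi among them, were evenly divided, 15 higher and 15 lower (median 0.019, percentile 83.3). Of the Notch list, Hes6, which is expressed in muscle precursors, was 1.41-fold higher while Hes1, Heyl (-0.31) and Dll1 (-0.20) were lower (median -0.057, percentile 10.2). Among immediate early genes the phosphatase gene Dusp4 was 1.73-fold higher, and Myc, Dusp5 (-0.52) and Nr4a2 (-0.48, up to 0.10 on its other probe sets) were lower (median -0.062, percentile 3.92). The TGF-β and BMP list stood apart in 2 of 13 settings and the immediate early list in 4. Egln3, an oxygen sensor, was 1.81-fold higher, while Slc2a1 (-0.38), Hk2 (-0.37) and Ndrg1 (-0.34) of the same glycolysis and hypoxia list were lower (median -0.00024, mean 0.018, percentile 63.1). Cholesterol synthesis genes were lower in 16 of 20 cases, led by Idi1 (-0.36), Insig1 (-0.31), Sqle (-0.29) and Mvd (-0.15), without standing apart (median -0.064, percentile 6.13), and spike-in scaling would make that median positive.

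Medians of the stress and inflammatory lists also lay within the range in the main setting. The NF-κB list (median 0.0051, mean -0.062, percentile 55.8) held Tnfaip3 at -0.53, Nfkbiz at -0.35 (-0.91 on its other probe set), Ptgs2 at -0.30 and Il1b at 0.21. With the mean of all probe sets this list stood apart on the low side (percentile 1.59). The interferon list (median -0.019, mean 0.029, percentile 29.1) held Ddx58 at 0.30, Bst2 at 0.21, Irf1 at -0.16 and Rsad2 at -0.14. The unfolded protein and amino acid response (median -0.017, percentile 31.7) held Pdia4 at -0.53, Vldlr at 0.19, Dnajb9 at 0.18 and Ddit3 at -0.13, with 0.42 on its other probe set. The heat shock and oxidative stress list (median 0.024, percentile 91.2) held Hspa1a at 0.42, Sqstm1 at 0.21 (0.07 as a mean over its probe sets), Hsph1 at -0.21 and Gclm at 0.18 (0.04 on its other probe set). Housekeeping genes had a median of -0.019 (percentile 31.6), with Actb at -0.16 on its brightest probe set and 0.33 on another, Tbp at -0.08, Hprt at -0.06 and Tfrc at -0.05.

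Markers of fibroblasts, leukocytes and endothelium were mostly below the floor, while 8 of 14 Schwann cell and 8 of 14 smooth muscle markers reached it. Of 18 fibroblast and fibro-adipogenic markers 4 were measured, Vim (-0.02), S100a4 (-0.06), Tcf7l2 (0.14) and Dpep1 (0.03), the first of which myoblasts also express. In the control Vim was at 14.88, S100a4 at 13.18 and Tcf7l2 at 9.74, all well above the floor, and Dpep1 at 6.09. Of 19 leukocyte markers 4 were measured, Laptm5 (-0.28), Lyz2 (at least 1.12-fold lower), Fcer1g (-0.15) and Csf1r (-0.03), none above 6.99. Both Laptm5 and Csf1r were higher on another probe set (0.21 and 0.36). Of 15 endothelial markers 5 were measured (median 0, mean -0.16, percentile 44.7), with Tek at least 1.12-fold lower and Eng at 0.08, Egfl7 at -0.07 (up to 0.07 on its other probe sets) and Flt1 at 0.03. The Schwann cell list (median 0.058, percentile 80.6) held Pmp22 at 0.18, Erbb3 at 0.13, Gfap at 0.11 and Mbp at -0.08. The smooth muscle list (median 0.048, percentile 89.2) held Acta2, Des, Mcam (-0.28) and Cspg4 (-0.22), the first 2 of which myoblasts express too. Among adipogenic genes Ppargc1a, also a muscle gene, was the only one changed, beside Cebpd (-0.23, and -0.09 as a mean over its probe sets), Cebpb (0.02) and Lpl (-0.01), and 4 were measured. Of the osteogenic and chondrogenic genes 4 were measured, Dlx3 (0.45, and 0.28 as a mean over its probe sets), Matn2 (at least 1.17-fold higher), Sox6 (0.16, and -0.01 as a mean over its probe sets) and Sp7 (-0.07). Of the sex-linked genes only Xist was measured, at 11.61 and 11.77, and the Y-linked genes were below the floor on both arrays.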

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

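Probe sets without a single gene name stand outside the gene comparison, and some of them were at least 2-fold higher with Wnt3a than in the control. Of 2464 such probe sets at the floor 7 were at least 2-fold higher and 2 at least 2-fold lower by their measured values, and 4 and 1 with the dimmer value raised to the floor. The largest difference was that of 1452004_at, which went from 4.42 to 8.72, a difference of 4.30, or at least 6.57-fold against the floor. Among those above the floor on both arrays was 1433471_at, 2.56-fold higher (7.43 to 8.78). The 2 lower probe sets were 1419675_at, 2.56-fold lower (9.60 to 8.25), and 1438441_at, at least 1.99-fold lower (6.99 to 5.53). No explanation was tested for these, and no gene is named for them here.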

How the results depend on the processing

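The count of genes at least 2-fold higher, 29, lay between 21 and 31, and that of lower genes, 7, between 4 and 7, under the settings that changed the floor, the probe set, the scaling among genes or the pseudocount, except for spike-in scaling. Taking the mean of all probe sets gave 4 lower genes. Spike-in scaling, added after seeing the data, gave 48 higher and 1 lower. A threshold of 1.5-fold gave 101 higher and 39 lower, and one of 3-fold 17 higher and 1 lower. Of the 29 higher genes, 21 were shared with the setting of all probe sets averaged and with the floor of 8, and 29 with quantile normalization and with the loess trend removed. Setting the median difference to 0 moved nothing, since it was 0 already, and spike-in scaling shifts a list and its random lists alike. Neither setting could move a list's percentile much, so they add little to the counts of settings. The Wnt feedback list kept its direction and stood apart in all 13 settings, with medians from 0.12 to 0.18, 0.35 under spike-in scaling, and a mean of 0.42. Spike-in scaling turned the median of the context-dependent Wnt targets to 0.14, of the G1/S genes to 0.11, of the extracellular matrix genes to 0.14 and of the ribosome biogenesis genes to 0.079, by its own construction, since it adds 0.19 to every difference. The mean of the context-dependent Wnt targets was 0.049, and the median of the p53 targets became -0.0019 without probe sets that can match several transcripts. The cause was not tested for the p53 list. Of 1674 values of the 162 named genes under alternatives, 1459 moved by less than the SD of 0.12 between probe sets, 161 moved by more under spike-in scaling and 54 under others. None of the 30 genes with the largest differences changed sign. They had been chosen by size and for probe sets of 1 sign, so this was nearly certain beforehand. Among the 162, 11 genes changed sign with the mean over all probe sets, without a floor (a check added after seeing the data), or without probe sets that can match several transcripts, each with a difference under 1.5-fold: Actb, Cenpf, Csf1r, Ddit3, Egfl7, Laptm5, Lpl, Mbp, Rps6, Rps9 and Sox6. No paired analysis was possible because each condition had 1 array, and no replicate could be left out for the same reason. Dim signal limits the genes whose control lay below the floor, 8 of the 29 higher ones.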

Other observations

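The genes in this part, and the tests of fewer dividing cells, of a response to Wnt3a in lung transcripts, of the lung transcripts at the floor alone and of unequal distributions, were chosen after the values had been seen.

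Several genes with large differences fell outside the lists. Beside Calcb, its receptor subunit gene Calcrl was 1.79-fold higher, while the accessory subunit gene Ramp1 differed by 0.01 (-0.34 on its other probe set). Beside Lifr, Jak2, a kinase that acts downstream of cytokine receptors, was 2.74-fold higher (1.45 and 1.49 on 2 probe sets). Car3, a muscle carbonic anhydrase, was 2.76-fold higher on its brightest probe set and by up to 3.80 on the log2 scale on others, and Car13 was 1.52-fold higher. The homeobox genes Irx3 and Irx5 were 3.11-fold and 1.67-fold higher. Metabolic genes at least 2-fold higher included Dio2, which activates thyroid hormone (2.66-fold, with 0.29 on another probe set and -0.16 on one below the floor), the glucose transporter gene Slc2a3 (2.74-fold) and the fatty acid activating enzyme gene Acsl3 (2.83-fold). Dimmer Slc2a3 probe sets, below the floor on both arrays, gave 1.31, 0.36 and -0.04.

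Regulators of growth factor signalling and of patterning moved in both directions. Spry1 (1.90-fold) and Lrig1 (2.23-fold), which restrain receptor tyrosine kinases, were higher, while Spry2 (0.0038) and Spry4 (0) hardly differed and Dusp6 was at -0.37. The patterning genes Zfp503 (2.11-fold), Gata3 (1.78-fold) and Gli3 (1.76-fold, with a difference of 0.16 on another probe set) were higher. Foxc1 (1.51-fold), Klf5 (1.55-fold, with 0.36 on another probe set) and Tshz3 (1.51-fold) were higher too. Foxc2 (1.51-fold) was lower, as were Prrx1 and Dmrt2. Foxo1 (1.52-fold), Bcl2l11 (1.73-fold, 5 probe sets of 1 sign), Nrp1 (1.60-fold, 4 probe sets of 1 sign) and Cxcl12 (1.58-fold, with -0.19 on another probe set) were lower. Of the Id genes, Id1 (-0.22), Id2 and Id4 were lower and Id3 (0.04) was not.

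Lower expression of the ribosome biogenesis genes accompanied the lower Myc. A trend with brightness was argued against as the whole cause, since random lists of the same brightness carry the same trend and the list's median of -0.11 lay below all of them, and since the fitted trend was small (a median move of 0.018 over measured genes, which left the list at -0.091 and percentile 0.01). A candidate explanation is the lower Myc, because nucleotide synthesis genes, another class of textbook Myc targets, were lower too relative to other genes (18 of 24, median -0.078, percentile 0.31). Spike-in scaling, which adds 0.19 to every difference, would turn that median positive and move all genes alike. Fewer dividing cells in the treated culture stays open, since the G2/M list lay at percentile 12.7, at 0.23 with the mean of all probe sets and at 29.5 by the list's mean, values on either side of what would favour or exclude it. The G1/S and DNA replication list was lower too (22 of 28, percentile 0.17 in the main setting). Fewer dividing cells could also lower nucleotide synthesis genes, so that list does not tell them apart from the lower Myc.

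Scgb1a1 and Sftpc, the transcripts of lung epithelium, were lower with Wnt3a. Lung RNA in the control array stays open: the 22 other lung epithelium transcripts had a median difference of 0.017 at percentile 42.0, but 15 of them were below the floor, where a lower level cannot show, so the bound set beforehand, which asked for few at the floor, was too weak. Of the 7 at the floor 4 were lower, with a median of -0.032 at percentile 25.6. Sftpb was at 7.05 and 7.14, and Cyp2f2 (4.45), Scgb3a2 (3.98), Sftpa1 (5.10) and Sftpd (4.85) were below the floor in the control. A response to Wnt3a cannot be told apart from a difference between single cultures with 1 array per group.

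More genes were higher than lower at the 2-fold threshold, by 29 to 7. Probe sets dim on both arrays were argued against as the cause, since the ratio of higher to lower genes was 3.50 at a floor of 8. That floor asks for 1 bright array only. Genes dim in the control alone, such as Calcb (4.79) and Syt13 (5.83), pass it, so it does not test these. Quantile normalization cannot decide on unequal distributions, since RMA, among the submitters' tools, in general already quantile normalizes probes. It left 29 higher and 6 lower genes (ratio 4.83) and moved no 2-fold changed gene by more than 0.03. The deposited distributions were thus already close to each other. Distributions before the submitters' processing cannot be seen here. An offset between the arrays stays open, since setting the median difference to 0 left the ratio at 4.14 because the median was already 0. The spike-in controls went against an offset that raised the Wnt3a array. All 42 were lower on it, and scaling on them gave 48 higher genes and 1 lower. Those controls come from the same single array per group, so they do not settle the question. A response that mainly raises transcripts is a hypothesis that 1 array per group leaves untested.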
